A study of Mus musculus with 2 samples.

How the data were processed

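The samples are total RNA from embryoid bodies of the CGR8 mouse embryonic stem cell line, grown without feeder cells, 1 sample in differentiation medium and 1 with FGF10 at 100 ng/ml, each labelled with biotin and hybridised to 1 Affymetrix expression array. The groups come from the sample titles. Nothing was pooled, and 0 columns of the table were left unused.

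The deposited values are MAS5 signal on a linear scale, per the submitters' processing notes, which name no version or settings. MAS5 combines perfect-match and mismatch probes into 1 value per probe set, which makes dim values noisy. The mean of each column without its lowest and highest 2% is 500.003, the form that scaling every array to a common target leaves. Such scaling removes a difference in total RNA between samples, so a gene's ratio is relative to the rest of its array. Detection calls were not used here. The number of arrays, 1 per group, limits the precision.

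Probe sets were named from the platform annotation. Of 45101 probe sets, 64 were chip controls, and of the other 45037, 34945 had 1 gene, 932 several and 9160 none listed. Of 35890 annotated probe sets, 34754 had a gene identifier found in the gene table for assembly GRCm38.p6, and 0 symbols were updated through it. The labels and the array values name no genome build, and no coordinates are given. Probe sets with several genes or none were left out of gene counts: 2558 of them passed the signal filter, 50 at least 2-fold higher and 48 lower. The streak gene T (Brachyury), 1 of the always-reported genes, has no named probe set and was not analysed here.

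The value for a probe set was log2 of the FGF10 signal over the control signal, with no offset, minus the median over kept probe sets (0.034). Kept probe sets had a mean signal at or above the median of all probe sets that are not controls (76.35), which left 22524, of which 19966 had 1 gene. A gene took the value of its brightest kept probe set, which gave 11122 genes. Across kept probe sets the arrays had a Pearson correlation of 0.977 and a Spearman correlation of 0.973, which are across probe sets, not replicates. Differences were counted at a fixed size of 2-fold, and of 1.5-fold within lists, with no test, since each group had 1 array. Technical SD is that of the difference in log2 ratio between the 2 brightest kept probe sets of a gene, divided by the square root of 2, over 5213 genes. It covers error within these arrays and says nothing of variation between cultures.

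Before the data were examined, 40 gene lists were fixed, along with the thresholds, the rule for named genes and the first set of alternatives. For each list the median log2 ratio of its kept members was set against 10000 random lists of the same size, matched on mean signal in 20 bins, and given a 95% interval from 2000 bootstrap draws over members. The interval and the percentile describe these arrays only. Percentiles were read for the 39 lists with at least 5 measured members. By chance 1.95 of them would lie outside the central 95%, and 7 lay above and 8 below. The random lists draw genes independently, so neither the 1.95 nor the percentiles allow for list members that vary together between cultures. Lists overlap, so they are not independent. Named genes are the 12 highest and 12 lowest whose kept probe sets all have the same sign and whose brighter signal is at or above the 60th percentile of its array, leaving out clone-like symbols, then up to 4 members of each list with the largest absolute ratio, and a fixed set of genes always reported. Other list members named in the text were chosen after their values were seen.

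The alternatives fixed in advance were no centring, quantile normalization, loess on mean signal, an offset at the 25th percentile, no signal filter, a filter at the 75th percentile, a filter on both arrays, the mean over probe sets, leaving out _x_at and _s_at probe sets, thresholds of 1.5-fold and 3-fold, leaving out each list's most extreme member, and the mean over members. Added after seeing the data were lists without the streak genes, lists read from each gene's second brightest probe set, and signals under 76.35 raised to that value before the ratio, with centring and members unchanged. The reading from second probe sets was run in 2 forms. The first form leaves out members with 1 kept probe set and turned the sign of 14 lists. The other form, which keeps those members at their only value, was added after the first form's result was seen, because the first also changes which genes a list holds, and both are reported.

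The procedure was tested on simulated arrays for this comparison, with 11208 genes passing the filter. With no replicates, the noise was normal with a spread set by the ratios between these 2 arrays. At 2-fold it recovered 49 of 50 genes with a true log2 ratio of 2, 42 of 42 at -2, 47 of 50 at 1.5 and 45 of 47 at -1.5, and 162 of 11019 unchanged genes passed. Each size was planted in 50 genes, and those that then fell under the signal filter are left out of these counts. The filter thus lost some of the genes made lower, and recovery among all planted lower genes was less complete. Of 100 lists of 20 unchanged genes drawn at random, 2 lay outside the central 95%, which does not test lists whose members vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.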

Results

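Gene expression was measured in embryoid bodies, the cell aggregates in which embryonic stem cells begin to differentiate, made in hanging drops from the mouse embryonic stem cell line CGR8 (strain 129). The comparison asks which transcripts differ when recombinant FGF10, a secreted fibroblast growth factor, is added to the differentiation medium at 100 ng/ml. There was 1 array from embryoid bodies in differentiation medium alone (control) and 1 array from embryoid bodies given FGF10. The labels date the samples to day 2, whereas the series' design text has RNA taken 24 h after treatment of embryoid bodies that were already 2 days old, so the stage is stated with that ambiguity. Each array gave a MAS5 signal for 45101 probe sets, with a median of 75.7 on the control array and 77.9 on the FGF10 array. With 1 array per group there is no replicate check, no p-value and no estimate of variation between cultures, and every ratio below describes this pair of arrays. Ratios are log2 of FGF10 over control.

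Genes of the primitive streak were among the highest on the FGF10 array. Mixl1, a homeobox gene of the streak, went from a signal of 238.2 on the control array to 3570.6 on the FGF10 array (a log2 ratio of 3.87, 14.6-fold), and Foxa2, a transcription factor of the anterior streak and endoderm, from 292.5 to 2563.4 (3.10). Of the 12 highest genes, 6 are in the list of primitive streak and mesendoderm genes: Mixl1, Foxa2, Sp5 (2.99), Cer1 (2.98), Mesp1 (2.68) and Gsc (2.46). The others were Aplnr, Ndrg1 (3.13), Ndufa4l2 (2.99), Cdh11 (2.62), Ctdspl (2.47) and Adamts9 (2.33, with a range of 1.52 to 2.33 over its probe sets). Aplnr, the apelin receptor, had signals of 54 and 1187.6 (4.42) and was at 2.32 on its other probe set, and Cer1 was at 5.03 on its other one. The control signals of Aplnr, Cer1, Ndufa4l2 and Ctdspl lay under the signal filter of 76.35, where a level may not be above background, so the size and order of their ratios are not known. With those signals raised to 76.35 their ratios were 3.92, 2.65, 1.36 and 1.28. Of 11122 genes measured, 147 were at least 2-fold higher and 144 at least 2-fold lower with FGF10, and 10831 lay within 2-fold. The dimmer of the 2 signals was under 76.35 for 52 of the higher and 70 of the lower genes, and with such signals raised to 76.35, 112 and 87 genes remained past 2-fold. Among members of the gene lists below, 70 were 1.5-fold higher and 59 lower, of which 68 and 55 remained so, all but Tnnc1, Asb4, Krt5, Pax6, Tek and Zeb1. The higher genes were the brighter ones, with a median mean signal of 213.75 against 130.5 for the lower genes. Among genes with at least 2 kept probe sets, 58 were 2-fold higher, and the second probe set had the same sign in 54 of them and was itself at least 1.5-fold higher in 43. For the 20 lower genes with a second probe set these numbers were 18 and 12. Over all 5213 genes with at least 2 kept probe sets, 65.7% had the same sign on both. The technical SD, taken from probe sets of the same gene, was 0.267 over all genes, 0.354 in the dimmest group and 0.161 in the brightest. In simulated arrays, 1.47% of the 11019 genes left unchanged passed 2-fold in either direction, while 1.32% of genes were higher and 1.29% lower here. The simulated noise was drawn from a normal distribution, its spread set by the ratios between these same 2 arrays, not by replicates. The 1.47% is therefore not a rate of false calls, and it does not tell how many of the genes counted here differ. Ratios spread most in the dimmest of 20 signal bins (SD 0.76), so a single dim gene past 2-fold is weak evidence of a difference.

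**Figure D1:**
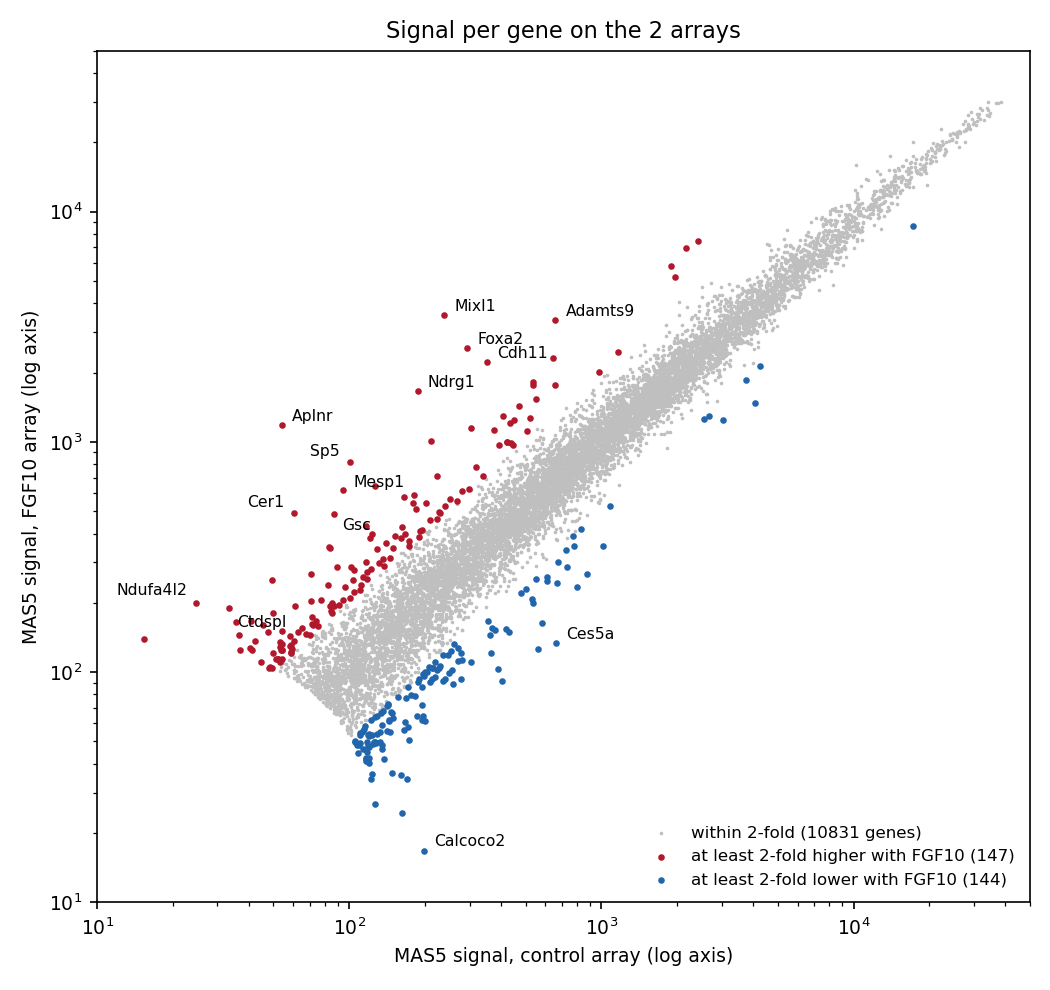
MAS5 signal of each of the 11122 genes on the control array (horizontal, log axis) and on the FGF10 array (vertical, log axis), 1 array per group and 1 point per gene, taken from its brightest probe set. The 147 genes at least 2-fold higher are red and the 144 at least 2-fold lower are blue, and most of the lower genes lie at the dim end, whereas Mixl1, Foxa2, Cdh11 and Adamts9 pass a signal of 2000 on the FGF10 array.

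Of 17 measured genes in the primitive streak and mesendoderm list, 15 were at least 1.5-fold higher with FGF10 and 0 lower. The list's median log2 ratio was 1.59 (95% bootstrap interval over members 0.89 to 2.68), above all 10000 random lists matched on signal (percentile 100). Besides Mixl1, Foxa2, Sp5, Cer1, Mesp1 and Gsc, they included Lhx1 (2.23), Fgf8 (1.81), the activin antagonist Fst (1.59), Eomes, which went from 1893.7 to 5783.5 (1.58), the BMP antagonist Chrd (1.19), Evx1 (1.17), Axin2 (0.89), Mesp2 (0.81) and Wnt3 (0.71). Nodal (0.34) and its inhibitor Lefty2 (-0.35) were the 2 members within 1.5-fold. The other 5 genes of the list, T (Brachyury), Wnt3a, Cdx1, Cdx2 and Cdx4, were below the filter or unnamed, so the result does not cover them. Of the 6 members with a second probe set, 5 were 1.5-fold higher, and the second probe set was so in all 5.

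The early and lateral plate mesoderm list had a median of 0.52 (interval -0.13 to 1.07, percentile 99.98) over 13 measured genes, of which 5 were at least 1.5-fold higher and 2 lower. Rspo3, an amplifier of Wnt signalling, had a ratio of 2.03, the repressor Snai1 1.63, the receptor gene Pdgfra 1.07 and Meis2 0.86, while Gata2 (-1.03) and Cited1 (-0.69) were lower. This list left the outer range without the signal filter (0.14, 27 members, percentile 91.41), at the stricter filter (0.086, 3 members) and without probe sets of the _x_at and _s_at types (0.043, 15 members). In the definitive endoderm and foregut list, 5 of 17 genes were higher and 1 lower, with a median of 0.14 inside the random range (percentile 96.87). Foxa2, Cer1 and Gsc belong to the streak list too, and the others were Cxcr4 (1.64) and Sox17 (0.68). After quantile or loess normalization the median was 0.19 in both cases and lay above the random range, as did the 0.70 of second brightest probe sets alone (5 members). It was 0.099 (percentile 93.9) without the 3 streak list members and 0.12 (percentile 92.3) with second probe sets put in where they exist. Genes of the epithelial to mesenchymal transition included Cdh11, a mesenchymal cadherin with ratios of 2.43 and 2.62 on its probe sets, Cdh2, which went from 980.3 to 2011.9, and Fn1 (0.74). In that list 4 of 19 were higher and 1 lower, and its median of 0.050 was within the random range (percentile 87.1). Cdh1, the epithelial cadherin, was at -0.10.

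Wnt pathway genes were also higher as a group. Of 22 measured, 8 were at least 1.5-fold higher and 0 lower, and the median was 0.44 (interval -0.00016 to 0.76, percentile 100). Dkk1 (1.01), Wnt8a (signals of 553.2 and 1132.8), Nkd1 (0.96) and Wnt11 (0.81) joined Sp5, Rspo3, Axin2 and Wnt3, and without the 3 genes shared with the streak list the median was 0.29 (percentile 99.95). Hedgehog genes had a median of 0.28 (interval -0.20 to 0.95, percentile 98.07) with 3 of 9 higher, namely Gas1 (1.73), Gli2 (0.95) and Cdon (0.78), and Shh was lower (-0.62). The other probe set of Gli2 was at -0.092. That result rested on few genes: without Gas1 the percentile was 89.5, without the signal filter it was 67, and with second brightest probe sets the median was -0.037. The Nodal and TGF-beta list (0.088, percentile 94.3, 3 of 20 higher and 1 lower), the BMP list (0.079, 87.7, 4 of 19 higher and 3 lower) and the Notch list (0.082, 78.2, 3 of 12 higher and 1 lower) lay within the random range, though the Nodal list passed above it without _x_at and _s_at probe sets (0.16, percentile 99.33). Within the BMP list the ligand Bmp2 was higher (1.18) and Smad1 was at 0.78, whereas the target genes Id1 (-1.09), Id2 (-1.32) and Id4 (-1.02) were lower and Id3 was at -0.012. Acvr1b (0.71) and Smad3 (0.59) were higher in the Nodal list and Gdf3 (-1.16) lower, and in the Notch list Hes1 was at 0.89, Jag1 at 0.75, Nrarp at 0.69 and Hes6 at -0.63. The retinoic acid list (8 genes, -0.089, percentile 16.2) held Cyp26a1 at 0.86 and Dhrs3 at 0.57 against Crabp1 at -0.78 and Rarg at -0.57. Probe sets disagreed in sign for Smad3 (-0.081 to 0.73) and Rarg (-0.57 to 0.27).

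Feedback and target genes of FGF signalling differed little at the 1 time sampled. The design text puts that time 24 h after treatment, so an earlier, passing response would not be seen. In the list of FGF and ERK feedback and target genes the median was 0.15 (26 genes, interval -0.12 to 0.25, percentile 99.09), but only Ier3 (1.86) was 1.5-fold higher and only Phlda1 (-0.65) lower. Spry4 was at 0.39, Egr1 at 0.47, Spry2 at 0.39, Dusp6 at 0.14 and Etv4 at -0.23. The probe sets of Spry4 (-0.57 to 0.39) and Etv4 (-0.23 to 0.43) disagreed in sign. With the mean over each gene's probe sets the percentile was 96.4, and on second brightest probe sets alone it was 90.5. Among ligands, receptors and cofactors the median was 0.024 (21 genes, percentile 66.9). Fgf8 was higher (1.81), Fgfr1 was at 0.60 on its brightest probe set and at 0.086 and 0.25 on its other probe sets, and Fgf4 (-1.56), Fgf15 (-0.69) and Fgfr3 (-0.70) were lower. The receptor gene Fgfr2 was at 0.087, with a dimmer probe set at -0.064. Fgf10 itself had signals of 40.8 and 49, both below the filter of 76.35.

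Cardiac genes were mixed, and many were too dim or unnamed to be measured, 15 of 25 in the list of transcription factors and 18 of 31 in the contractile list. In the list of cardiac progenitor and cardiac transcription factors the median was -0.011 (10 genes, percentile 42.2). Mesp1 and Fgf8, shared with the streak list, and Gata6 (0.96) were higher, and Hopx was lower (-0.85). Nkx2-5 had dim signals of 91 and 72 (-0.37), Gata4 was at -0.47 on one probe set and 0.29 on another, and Isl1 lay below the filter. In the contractile and natriuretic list 1 of 13 measured genes, Tnnc1 (0.61), was higher and 4 lower, with a median of -0.28 (interval -0.63 to -0.15, percentile 1.7). Mybpc3 (-1.27), Acta2 (-0.96), Myl9 (-0.72) and Actn2 (-0.63) were the lower ones, Myh6 was at -0.16, and Tnnt2 was below the filter. That call ended in 5 of the settings tried, among them no signal filter (-0.24, 30 members, percentile 6.06). In the endothelial and haematopoietic list 5 of 12 genes were lower and 2 higher, with a median of -0.57 (interval -0.66 to -0.12, percentile 0). Tal1 (-1.03), Tek (-0.77) and Eng (-0.70) were among the lower genes and Flt1 (0.91) and Sox17 among the higher. At the stricter filter only 3 members were left, with a median of 0.0070, and second brightest probe sets alone gave -0.046 over 5 members, whose brightest probe sets gave -0.030. In each of the 5 the 2 probe sets shared a sign. With second probe sets put in where they exist, all 12 members gave -0.59 (percentile 0).

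**Figure D2:**
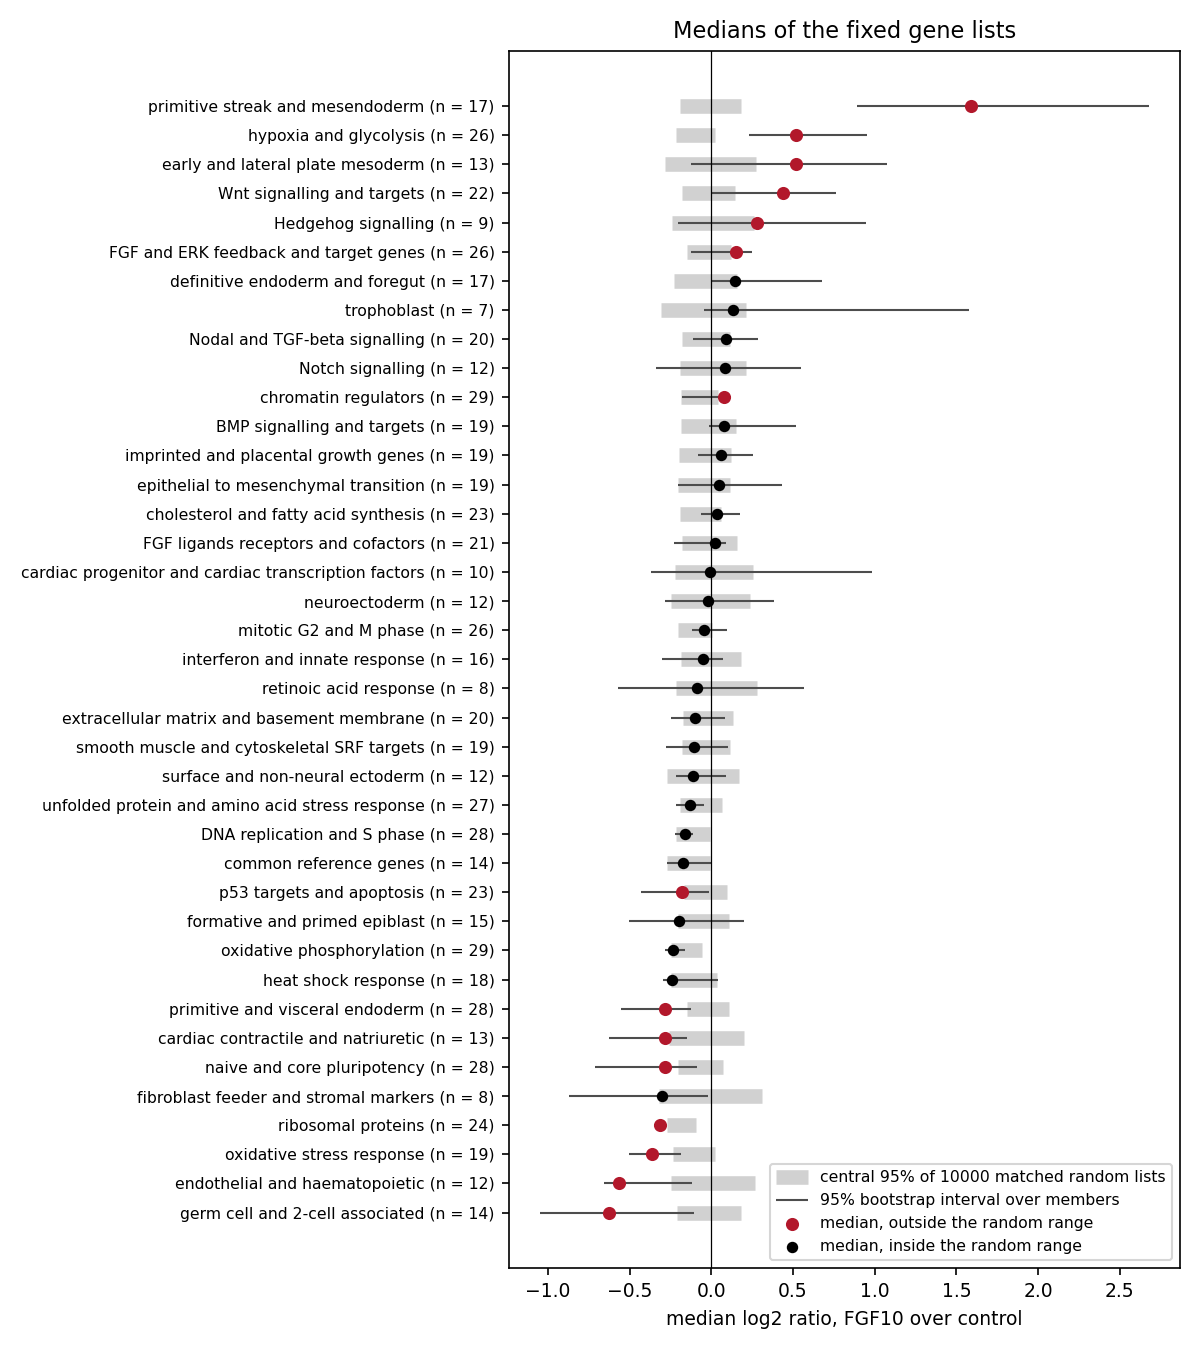
Median log2 ratio (FGF10 over control, horizontal) of the 39 fixed gene lists with at least 5 measured members, with n the number of measured genes. Points are medians over 1 array per group, thin lines the 95% bootstrap interval over members, grey bars the central 95% of 10000 random lists matched on signal, and red points lie outside it. The primitive streak list, at 1.59, is far above its grey bar and the germ cell list, at -0.63, is lowest.

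The core pluripotency factors were close to equal on the arrays, while a set of other pluripotency-associated genes was lower with FGF10. Pou5f1 was at 0.073, Nanog at 0.22 and Sox2 at -0.0026. Of 28 measured genes in the naive and core pluripotency list, 0 were 1.5-fold higher and 10 lower, with a median of -0.28 (interval -0.71 to -0.090, percentile 0.07). Dppa2 went from 4084.7 to 1474.4 (2.84-fold lower) and Dppa5a from 17188.2 to 8648.7 (-1.03), and Gdf3 (-1.16), Rex2 (-1.16), Dppa3 (-1.07), Nr5a2 (-1.01), Dppa4 (-0.97), Utf1 (-0.73), Zfp42 (-0.71) and Nr0b1 (-0.71) were the others. With second brightest probe sets alone, which exist for 10 members, the median was 0.011 (percentile 46.5) against -0.24 for the brightest probe sets of the same members, while with them put in where they exist it was -0.25 over all 28 (percentile 0.74). The 3 lower members that have a second probe set, Dppa2, Gdf3 and Utf1, were 1.5-fold lower on it too.

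Formative and primed epiblast genes had a median of -0.20 (15 genes, percentile 2.70), just within the random range, with Cdh2 and Zic2 (0.59) higher and Dnmt3l (-1.16), Fgf15 and Pou3f1 (-0.67) lower. Fgf5 (0.19) and Otx2 (0.20) were within 1.5-fold. The list passed below the 2.5th percentile after quantile (0.32) or loess (0.21) normalization. With second brightest probe sets alone its median was 0.11 (8 members, percentile 86.5), and with them put in where they exist it was -0.041 over all 15 (percentile 51.9). In the germ cell and 2-cell associated list 8 of 14 genes were lower and 1 higher, with a median of -0.63 (interval -1.05 to -0.10, percentile 0). Usp17la (-2.17), Mael (-1.48), Dazl (-1.16), Rhox5 (-1.03), Ddx4 (-0.83) and Ifitm3 (-0.63) were lower, and Tfap2c was higher (1.66). Only 4 members have a second probe set, and those gave 0.21 (percentile 77.8) against -0.061 for the brightest of the same 4, each gene having 1 sign on both. With second probe sets put in where they exist the median was -0.55 over all 14.

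Genes of the primitive and visceral endoderm, the extraembryonic layer that lines embryoid bodies, were lower as a group. Of 28 measured, 8 were at least 1.5-fold lower and 3 higher, with a median of -0.28 (interval -0.55 to -0.12, percentile 0). The lower genes included Apoa1 (-1.27), Rhox5, Hnf4a (-0.90), Cubn (-0.76) and Ttr (-0.63). Pdgfra, Gata6 and Sox17, which mesoderm or definitive endoderm express as well, were the 3 higher ones. Afp was at -0.15 and Dab2 at -0.59, and probe sets disagreed in sign for Hnf4a (-0.90 to 0.15) and Afp (-0.24 to 0.18). Second brightest probe sets alone, for 16 members, gave 0.17 (percentile 94.9) against -0.15 for the brightest of those members, and put in where they exist gave -0.19 over all 28 (percentile 0.89).

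Hypoxia-inducible genes were higher with FGF10. In the hypoxia and glycolysis list 12 of 26 measured genes had a log2 ratio past 1.5-fold upward and 0 downward, with a median of 0.52 (interval 0.23 to 0.96, percentile 100). Ndrg1 went from 186.5 to 1667 (3.13, with 2.49 to 3.38 over its 5 probe sets), Aldoc was at 1.70, the oxygen sensor Egln1 at 1.45 and Ddit4, an inhibitor of mTORC1 signalling, at 1.37. Adm (1.15), Egln3 (1.08), Ero1a (1.05), P4ha1 (1.04), Bnip3 (0.96), the glycolytic enzyme genes Pfkl (0.88) and Pfkp (0.85) and the glucose transporter gene Slc2a1 (0.61) were the others. Ldha (0.011) and Pkm (-0.049) were near 0, as was Pdk1 (-0.028), whose 3 probe sets ran from -0.062 to 0.36. In each of the 15 members with a second probe set, it had the sign of the brightest one.

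**Figure D3:**
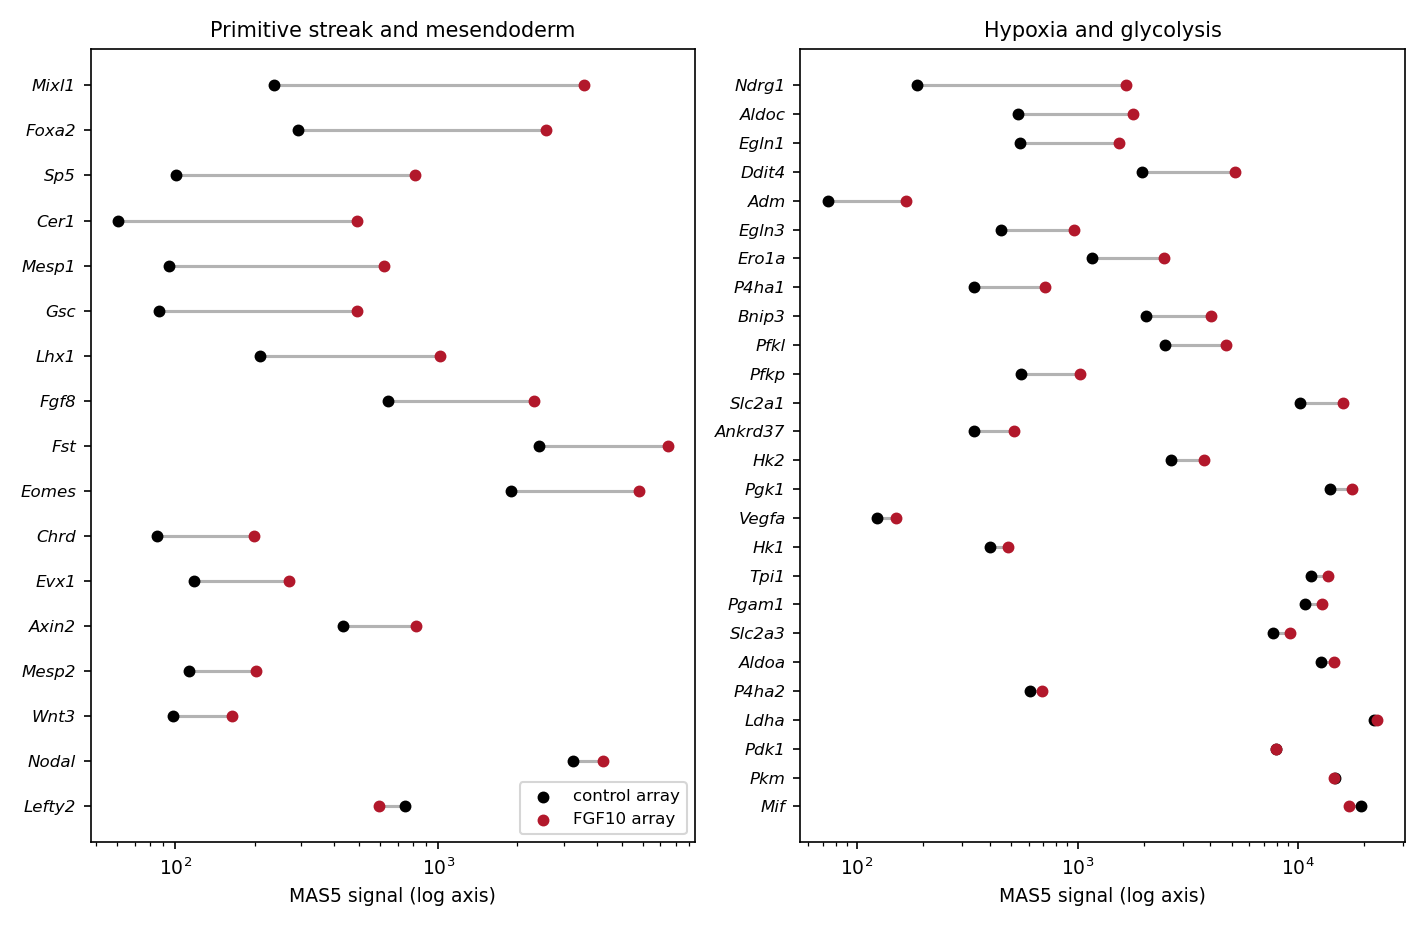
MAS5 signal (horizontal, log axis) of each measured gene in the primitive streak and mesendoderm list (left, 17 genes) and the hypoxia and glycolysis list (right, 26 genes) on the control array (black) and the FGF10 array (red), 1 array per group. Genes are ordered by log2 ratio, from Mixl1 at 3.87 to Lefty2 at -0.35 on the left and from Ndrg1 at 3.13 to Mif at -0.22 on the right.

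The lowest single genes on the FGF10 array were mostly dim and read by 1 probe set. Calcoco2, an autophagy receptor, had signals of 198.2 and 16.8 (-3.59), Zbp1 was at -2.76, Sry, on a probe set of the _x_at type, at -2.34, Ces5a at -2.34 and Tex12, a gene of meiotic chromosomes, at -2.20. Usp17la followed, then Slc25a31 (-1.87), Rasgrp2 (-1.81), Taf7l (-1.80), Lce3b (-1.73), Mcam (-1.69) and Sned1 (-1.65). The FGF10 signals of 8 of the 12 lay under 76.35, so the size and order of those ratios are not known. Raised to 76.35, they gave -1.41 for Calcoco2, -1.12 for Zbp1, -1.19 for Sry, -1.11 for Tex12, -1.21 for Taf7l, -1.42 for Lce3b, -1.38 for Mcam and -1.40 for Sned1. Rasgrp2 is the only one of these 12 outside the dimmest group of genes and the only one with other kept probe sets, the nearest to 0 of which was at -0.30.

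At the main setting, markers of other lineages and of feeder cells lay within the random range. The neuroectoderm list had a median of -0.018 (12 genes, percentile 46.5), with Zic5 (0.62) and Zic2 higher and Pax6 (-0.95) and En2 (-0.65) lower. Surface ectoderm genes were at -0.11 (12 genes, percentile 33.0), trophoblast genes at 0.13 (7 genes, percentile 93.4) and fibroblast feeder and stromal genes at -0.30 (8 genes, percentile 3.28), which passed below the random range in 5 settings. The neuroectoderm list passed above it at the filter at the 75th percentile (0.30, 5 members, percentile 97.8) and the trophoblast list on second brightest probe sets alone (0.47, 5 members, percentile 99.6). Tfap2c (1.66) and Krt19 (0.72) were higher, and Phlda2 (-0.97) was lower. In the feeder list Tagln was at -0.87 and Thy1 at -0.61 against Pdgfrb at 1.97. The control signal of Pdgfrb, 36.4, lay under 76.35, and with it raised to that value the ratio was 0.90. Hoxa5 was the 1 Hox gene measured and was at -0.52.

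Several reference genes and the hybridisation spikes were slightly lower on the FGF10 array, while other controls were higher. The control probe sets for the transferrin receptor were at 0.053 to 0.40, and in the reference list Polr2a was at 0.36 and Pgk1 at 0.29. The log2 ratio of Actb was -0.25, with signals of 25255.8 and 21695.6, and 0.028 after quantile normalization. The control probe sets for Gapdh had ratios of -0.27 to -0.30, and the common reference list had a median of -0.17 (14 genes, percentile 38.4) that was 0.0034 after quantile normalization. The 18 hybridisation spikes, which are added in equal amount, had a median of -0.20. The BioB spikes, at mean signals of 535.25 to 892.5, were at -0.14, while the 1549 genes in that range had a median of 0.021. The 557 genes of the brightest signal bin were at -0.20. RNA quality was alike: the ratio of the 3' to the 5' probe set was 1.27 and 1.23 for Actb and 0.812 and 0.811 for Gapdh on the control and FGF10 array.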

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

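The lists read from second brightest probe sets or without streak genes, and the raising of dim signals, were chosen after seeing the data, and all other settings before. Of 551 list medians under alternatives, 47 had the opposite sign to the main value. Of these, 39 belong to lists within the random range, where the sign is not read, and 8 to lists outside it. Apart from those 8, 524 medians stayed within the bootstrap interval of the main value and 19 left it. The streak, hypoxia and Wnt lists stayed above the random range in every setting that gave a percentile. Among 1333 values of 159 named genes, 54 moved by more than the technical SD, 0 of the 2-fold ones changed sign, and 98 could not be had because the setting removed the gene. No scaling moved the median of all genes by over 0.034. Counts depend on the signal filter: at 2-fold, 1459 genes were higher and 1805 lower without the signal filter, 42 and 14 at the 75th percentile, and 96 and 73 with both arrays above their median. With signals under 76.35 raised to that value, 112 were higher and 87 lower, and no list entered or left the random range. At 1.5-fold there were 602 and 540, and at 3-fold 43 and 26. Without the filter the correlation was 0.936 and the technical SD 0.844, at the 75th percentile the SD was 0.174, and without _x_at and _s_at probe sets 0.294.

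Second brightest probe sets alone, which leave out members with 1 kept probe set, turned the sign of 14 lists. The 5 of them called outside the random range were the pluripotency (0.011), cardiac contractile (0.0023), visceral endoderm (0.17), germ cell (0.21) and Hedgehog (-0.037) lists, and the other 9 included the formative epiblast (0.11), Notch (-0.21) and retinoic acid (0.27) lists. They took outside their interval the endothelial (-0.046), definitive endoderm (0.70), FGF ligand (0.10), BMP (-0.025), mitotic (0.12), cholesterol (0.20), ribosomal (-0.25), imprinted (0.28) and chromatin (0.12) lists. This form was run first. With the later form, which keeps all members, 8 lists turned, of which only the Hedgehog list (-0.037) was called, and fewer members change their value by construction, so it is the milder of the 2. The medians of the pluripotency (-0.24 against 0.011) and visceral endoderm lists (-0.15 against 0.17) differ between probe sets of the same members, so membership does not account for the whole change. Whether dim second probe sets are the cause was not tested.

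Quantile normalization gave -0.079 for DNA replication, -0.044 for oxidative phosphorylation, -0.014 for ribosomal proteins and 0.0034 for reference genes, and loess gave -0.066, -0.049 and -0.069 for the first 3, since both remove the trend with brightness. The filter at the 75th percentile gave 0.0070 for the endothelial list with 3 members and 0.12 for FGF ligands. Leaving out _x_at and _s_at probe sets gave -0.070 for trophoblast genes. The mean over members was -0.021 for chromatin regulators and -0.040 for the unfolded protein list. The cause of these was not tested. List percentiles left the outer range 28 times and entered it 23 times.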

Other observations

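The tests of second probe sets, of epiblast markers and of glycolytic enzymes were chosen after the results were seen. Genes of the oxidative stress response, many of them targets of the transcription factor Nrf2, were lower on the FGF10 array. Of 19 measured, 3 were at least 1.5-fold lower and 0 higher, with a median of -0.36 (percentile 0.01), and on second brightest probe sets the median was -0.40 over 12 members, each gene having 1 sign on both probe sets. Nqo1 was at -0.83, Srxn1 at -0.65 (0.19 on another probe set), Gclm at -0.59 and Hmox1 at -0.58. In the p53 and apoptosis list Mdm2 was lower (-0.75, and -0.43 on its other probe set). Bcl2l11 was higher (0.80, with 0.031 to 0.80 over its 5 probe sets). The median of the p53 list was -0.18 (23 genes, percentile 1.81). It returned to the random range on the mean over probe sets (percentile 4.27), without _x_at and _s_at probe sets (9.76) and on second brightest probe sets in both forms. Chromatin regulators had a median of 0.079 (29 genes, percentile 99.58) but a mean of -0.021, and returned to the random range at the filter at the 75th percentile (96.8) and with second probe sets put in where they exist (95.9). Kdm5b (0.59) was its 1 gene past 1.5-fold upward and Dnmt3l (-1.16), a DNA methylation cofactor, its 1 gene past it downward. Hells was at -0.56, Dnmt3b at -0.50 and Dnmt3a at -0.52, with 5 probe sets of Dnmt3a from -0.52 to 0.53.

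Ribosomal protein genes were at -0.31 (24 genes, percentile 0.1), a value that fell within the random range after quantile normalization (-0.014) or loess (-0.069). Oxidative phosphorylation genes were at -0.23 (29 genes, percentile 4.8), heat shock genes at -0.24 (18 genes, percentile 3.32, and 0.45 with second probe sets put in where they exist), DNA replication genes at -0.16 (28 genes, percentile 21.7) and mitotic genes at -0.043 (26 genes, percentile 86.5). With second probe sets put in, the mitotic list turned to 0.075 (percentile 99.63). None of these 5 lists, on brightest probe sets, held a gene past 1.5-fold in either direction. Cholesterol and fatty acid synthesis was at 0.033 (23 genes, percentile 94.4, and 99.31 on the mean over probe sets), the unfolded protein response at -0.13 (27 genes, percentile 16.3) with Vldlr at 1.78, interferon genes at -0.051 (16 genes, percentile 31.5) with Gbp2 at -0.64, and extracellular matrix at -0.099 (20 genes, percentile 15.4) with Nid1 at 0.64 on one probe set and -0.16 on another. Smooth muscle and SRF targets were at -0.11 (19 genes, percentile 15.8), with Tagln, Acta2 and Myl9 lower, and imprinted genes at 0.059 (19 genes, percentile 88.7), with Asb4 at 0.72 and Cdkn1c at -0.88.

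The first pattern weighed is the higher primitive streak list. A trend with signal does not account for it, since after loess the median was 1.69. Noise of single probe sets is argued against only for the 6 members that have a second probe set. Their second probe sets had a median of 1.63 and all 6 lay above 0. For the other members, among them Mixl1, Foxa2, Sp5, Mesp1 and Gsc, such noise stays open, since each has 1 kept probe set. A hypothesis that stays open, since 1 culture per group cannot tell stage from treatment, is that the FGF10 culture may have been further along in differentiation than the control. The formative and primed epiblast list should then be lower, and it was at percentile 2.695, just inside the random range, and below it after loess (0.21), after quantile normalization (0.32), without the filter (2.21) and with the filter on both arrays (2.36). It lay further inside on second probe sets alone (86.5) or put in where they exist (51.9), on the mean over probe sets (10.4), at the filter at the 75th percentile (7.29), without its most extreme member (6.95) and without _x_at and _s_at probe sets (6.19).

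The higher hypoxia and glycolysis list is the second pattern. It was 0.53 after loess, so a trend with signal does not account for it. A list of 24 other measured hypoxia-inducible genes, written before their values were looked at, had a median of 0.38 (percentile 100) with 8 higher and 1 lower. Pfkfb3 (1.38), Bhlhe40 (1.02) and Kdm3a (0.72) were among the higher ones and Angptl4 (-0.71) was the lower one. Tmem45a (-0.32) and Pfkfb4 (-0.24) were also below 0. The list's median goes with a wider hypoxia-inducible programme as a hypothesis. A shift in glycolysis alone is argued against, since the 12 members other than glycolytic enzymes and glucose transporters had a median of 1.04. Not all of them were higher: Ankrd37 (0.57), Vegfa (0.24), P4ha2 (0.15) and Mif (-0.22) lay within 1.5-fold. The 14 enzymes and transporters, with Pdk1 counted among them, had a median of 0.24, a difference of -0.81. That split was not matched on signal. Enzyme genes such as Ldha, Pkm and Pgk1 are very bright, and ratios spread little in the brightest bin (SD 0.19), so the size of the difference is not read. Whether FGF10 or the oxygen supply of 1 culture, such as the size of its aggregates, is the source was not tested, and the design confounds them.

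The lower pluripotency-associated and germ cell lists are the third pattern. The germ cell list was at -0.62 after loess, so a trend with signal does not account for it. Of a list of 35 other germline genes, written before their values were looked at, 13 were measured. Their median was -0.34 (percentile 0.73), with 4 lower and 0 higher, including Stk31 (-0.94) and Asz1 (-0.84). The FGF10 signals of Stk31 and Asz1, 62 and 57.6, lay under 76.35, so the size of their ratios is not known. Raising dim signals was not tried on this list, so the count of 4 is uncertain. Noise of single probe sets stays open for the pluripotency list: second probe sets of 10 members had a median of 0.011, with 5 of them above 0, although Dppa2, Gdf3 and Utf1 were lower on both. A hypothesis is that a set of germline-type genes still active in stem cells may have been lower in the FGF10 culture while Pou5f1 and Sox2 were not, and it needs further cultures to be tested.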
